A study of Mus musculus with 15 samples.

How the data were processed

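Total RNA of lung lobes kept in RNAlater was sequenced for 15 mice, 5 in each of 3 groups, after library preparation with a stranded total RNA kit. The deposited table holds raw counts per Ensembl gene, 1 column per library, made by the authors with STAR 2.5.3a on genome build GRCm38 per the submitters' processing notes. The counting tool, its strand setting and the annotation release are not given in the sources used here, so genes that overlap others may hold reads of their neighbours. The counts are whole numbers with totals from 17182599 to 44201637 per library. Gene coordinates were taken from an annotation of GRCm38.

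Genes were filtered with edgeR's filterByExpr, which kept 19562 of 55421, and libraries were scaled by TMM factors. The 3 comparisons (short-term against HDM, long-term against HDM, short-term against long-term) and an F test over all 3 groups were contrasts of a single fit of all 15 libraries with edgeR 4.0.16 quasi-likelihood tests with robust shrinkage, in R 4.3.3. p-values were two-sided and adjusted by the Benjamini-Hochberg (BH) method, and genes at an adjusted p under 0.05 are called. Expression is given in CPM with TMM-scaled library sizes. Replicate numbers follow the order of the deposited samples and pair nothing.

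Before the data were examined, 49 gene lists, a panel of 22 asthma genes, the comparisons and most alternatives were fixed. The 47 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted by BH. Genes are named by a fixed rule. Per comparison these are up to 8 called genes with the highest and up to 8 with the lowest log2 fold change at a mean of at least 1 CPM, leaving out predicted genes, pseudogenes and antigen receptor variable segments. Where no gene passed, the 5 with the smallest p in each direction are named as not past the test. The panel genes and up to 4 members of each called list, or 3 of another list, complete the rule. Shares of library composition were compared by exact two-sided permutation of 5 against 5 libraries in Python 3.11.15, adjusted by BH over 18 tests. Figures were drawn with matplotlib 3.10.9.

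The tests were tried on simulated data with known changes, drawn at the depth and spread of these libraries. For planted changes of 1.5, 2 and 4-fold, 35.8%, 77.6% and 95.5% were recovered for short-term against HDM, 40.3%, 80.6% and 98.5% for long-term against HDM, and 43.3%, 79.1% and 97% for short-term against long-term. False calls were 4.6%, 4.5% and 3.8% of the calls, and besides the planted list 1, 0 and 1 of 47 lists were called. In these draws genes varied independently of one another, with the same spread per gene in all libraries. In the real libraries the estimated correlation was, for example, 0.642 for the B-cell list (short-term against HDM). The simulated list calls therefore give no rate of false calls for lists whose members move together. The folds of 1.5, 2 and 4 were planted only in genes with a mean of at least 1 CPM. Spread also differed between the real libraries: the limma voom quality weight was 0.134 for short-term replicate 3 and 0.257 to 2.666 for the others. The shares recovered and the shares of false calls need therefore not hold for the real gene calls.

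The alternatives were RLE and upper-quartile scaling, no filter on low counts, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma voom with sample quality weights, a fit without robust shrinkage, 1 surrogate variable from sva 3.50.0, a fit of only the libraries compared, a fold change of at least 1.5, and leaving out each library in turn. Fits without HDM replicates 1 and 2, fits that left short-term replicate 3 out beyond the planned turn of each library, and loess corrections for transcript length and GC content were chosen after seeing the data. The correlation of both MSC effects was compared with 50 simulations in which neither group changed and with splits of the HDM libraries. All 15 libraries were kept in the analysis, since no reason to exclude one is given in the sources used here. Saline-treated mice named in the design text were not analysed here.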

Results

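Total RNA was sequenced from lung lobes of 15 female C57BL/6 mice with airway inflammation driven by house dust mite (HDM) extract, a mouse model of allergic asthma. Each mouse was given 10 µg of extract through the nose on 5 days of each of 2 weeks, and the lungs were taken on day 15. The mice formed 3 groups of 5: HDM alone, HDM with mesenchymal stem cells (MSCs) from adipose tissue given through the nose on day 6 (the long-term group), and HDM with MSCs given on day 13 (the short-term group). MSCs are stromal cells that can be grown in culture and that secrete mediators acting on immune and epithelial cells. The design text names saline-treated mice, which were not analysed here, so every value is relative to inflamed rather than healthy lung. Total counts ranged from 29635897 to 44201637 in the HDM libraries, from 31762964 to 41762167 in the long-term libraries and from 17182599 to 32119067 in the short-term libraries. Of 55421 genes in the table, 46542 had a count in some library and 19562 were tested.

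One short-term library, replicate 3, stood apart from the other 14. It held 17182599 counts, the lowest total, yet had counts for 43174 genes, against 26542 to 29154 in the others. Thymocyte genes were high in it: Rag1, part of the recombinase that assembles antigen receptors, reached 1951 CPM, against at most 7.07 CPM in the other 4 short-term libraries. Transcripts from satellite repeats (Gm10800, Gm10801 and Gm21738) took 15.8% of its counts, against at most 0.0420% in any other library. The first principal component of the libraries, with 33.2% of the variance, placed this library at -111 and the others between -21.3 and 27.6. The second component, with 18% of the variance, placed HDM replicates 1 and 2 at 40.9 and 54.5, above all other libraries. Values without short-term replicate 3, and without HDM replicates 1 and 2, are therefore given beside the gene groups that move with them.

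**Figure D1:**
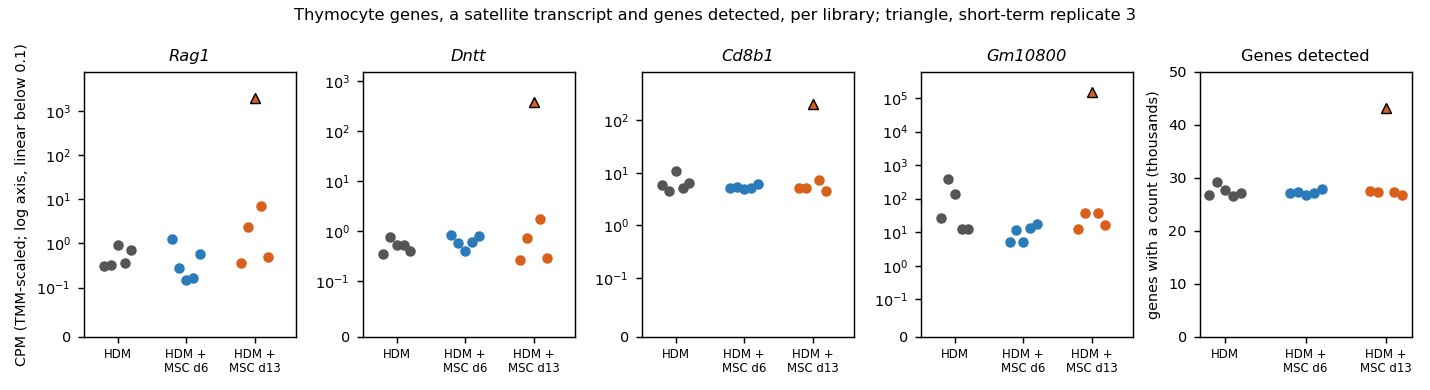
Expression of 3 thymocyte genes and a satellite transcript (CPM, log axis that is linear below 0.1) and number of genes with a count, for each of the 15 libraries by group. Short-term replicate 3 (triangle) reached 1951 CPM for Rag1 and 150006 CPM for Gm10800, and had counts for 43174 genes.

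The comparison of the short-term group with HDM alone asks what MSCs given late in the challenge do to the inflamed lung. B-cell genes were lower in the short-term group: Cd79b, a signalling chain of the B-cell receptor, averaged 36.7 ± 11.9 CPM (mean ± SD, n = 5) against 76.8 ± 4.10 CPM in HDM (n = 5). Eln, which encodes elastin, averaged 358 ± 150 CPM against 1265 ± 551 CPM (n = 5 each), and Csf2, the growth factor GM-CSF of macrophages and granulocytes, averaged 7.25 ± 1.21 CPM against 18.3 ± 8.26 CPM (n = 5 each). The Csf2 mean of HDM rests in part on replicates 1 and 2, without which its log2 fold change was -0.75 (adjusted p = 0.0376), against -1.33 with all libraries. Gene lists of antigen presentation, monocytes, neutrophils, type 2 alveolar epithelium and the mitochondrial genome were lower as well by camera at a preset correlation, with adjusted p from 0.515 to 0.625 with an estimated correlation. The monocyte and neutrophil medians shrank to -0.18 and -0.10 without short-term replicate 3. Il13, a cytokine of type 2 inflammation, and Muc5ac, a mucin of inflamed airways, did not pass the test in either direction.

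With edgeR's quasi-likelihood test, 937 of 19562 genes passed an adjusted p of 0.05 between the short-term group and HDM, 371 higher and 566 lower in the short-term group. Of these, 464 differed by at least 1.5-fold (275 higher, 189 lower), and 676 were protein-coding. The median log2 fold change of all tested genes was 0.03; with upper-quartile normalization it was 0.09, and 481 genes were higher and 298 lower. The count was 1294 (634 higher, 660 lower) without short-term replicate 3, 449 without HDM replicate 1, 259 without HDM replicate 2, 375 without HDM replicate 4, 378 without short-term replicate 2 and 160 without short-term replicate 5. It was 183 without HDM replicates 1 and 2 together, and 0 when only the 10 libraries of both groups were fitted (3494 genes at an unadjusted p under 0.05). DESeq2 called 2136 genes and limma voom 2412. Of 51 called genes named in the text, 16 passed whichever library was left out and 35 lost their call without at least 1, each with an adjusted p of at most 0.116. These 51 were picked mostly for large fold changes or small p, so they do not stand for all calls. Of the 937 calls, 17% were kept without short-term replicate 5 and 26.4% without HDM replicate 2.

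The B-cell list fell most clearly by its test. All 13 tested members lay below 0 with a median log2 fold change of -0.94, and 10 fell past the test over all genes, or 13 adjusted over the list alone. The list test (camera) gave an adjusted p of 6.5e-21, and adjusted p = 0.201 with an estimated correlation. Fcrla (ENSMUSG00000038421, GRCm38 chromosome 1, 170917576 to 170927583), an Fc receptor-like protein of B cells, fell by 1.12 on the log2 scale (SE 0.16, adjusted p = 0.00578), from 20.99 ± 3.66 to 9.64 ± 2.51 CPM (n = 5 each). Cd79b (ENSMUSG00000040592, chromosome 11, 106311341 to 106314762) fell by 1.06 (SE 0.17, adjusted p = 0.00904). Ms4a1, which encodes the B-cell surface protein CD20 (ENSMUSG00000024673, chromosome 19, 11249675 to 11266241), fell by 0.94 (SE 0.16, adjusted p = 0.0109), from 61.3 ± 12.5 to 31.9 ± 7.15 CPM (n = 5 each). Fcmr, the receptor for IgM, fell by 1.03 (SE 0.18, adjusted p = 0.0109). For each of these 4 genes all 5 short-term libraries lay below the lowest HDM library. These genes passed whichever single library was left out. Without HDM replicates 1 and 2 the median of the list was -0.77, and Ms4a1 (adjusted p = 0.05001) and Fcmr (adjusted p = 0.0531) did not pass.

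Antibody genes followed. The plasma-cell list had a median of -1.10 over 17 tested members, all below 0. Of these, 3 fell past the test over all genes and 12 adjusted over the list alone (camera adjusted p = 1.2e-10, and adjusted p = 0.270 with an estimated correlation). The constant-region genes Iglc2, of a lambda light chain (chromosome 16, 19198396 to 19200351), Ighg2b, of IgG2b, and Igkc, of the kappa light chain, had log2 fold changes of -1.39 (SE 0.20, adjusted p = 0.00549), -1.41 (SE 0.33, adjusted p = 0.0282) and -2.09 (SE 0.52, adjusted p = 0.0355). Igkc averaged 721 ± 542 CPM in the short-term group and 3078 ± 1957 CPM in HDM (n = 5 each). Of 156 tested immunoglobulin variable segments, 144 lay below 0, 15 were called lower and none higher, with a median of -1.55. Immunoglobulin genes took 0.280 ± 0.196% of the counts in the short-term group and 0.880 ± 0.432% in HDM (n = 5 each), an exact two-sided permutation p of 0.0159 (0.0857 adjusted over 18 tests of library composition). Within HDM that share ran from 0.322% in replicate 3 to 1.54% in replicate 2. Without short-term replicate 3, Igkc (adjusted p = 0.0721) and Ighg2b (adjusted p = 0.0581) no longer passed, nor did either without HDM replicates 1, 2 or 4 or short-term replicates 2 or 5, or Ighg2b without HDM replicate 5 (largest adjusted p 0.0873 for Igkc and 0.0765 for Ighg2b, both without short-term replicate 5).

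Lists of lymphoid follicles and of antigen presentation by MHC class II were lower too. The follicle list had a median of -0.51 over 10 tested members, with 2 lower over all genes and 5 adjusted over the list alone (camera adjusted p = 4.4e-05, and adjusted p = 0.270 with an estimated correlation). Its called members were Cxcr5, the receptor that brings B cells into follicles, at -0.87 (SE 0.15, adjusted p = 0.0109), and Cr2, the complement receptor CD21, at -0.98 (SE 0.24, adjusted p = 0.034). Without HDM replicates 1 and 2 Cr2 was at -0.46 (adjusted p = 0.165) and the follicle median was -0.44. The MHC class II list had a median of -0.33, with all 14 members below 0, 4 lower over all genes and 6 adjusted over the list alone (camera adjusted p = 5.4e-07, and adjusted p = 0.515 with an estimated correlation). H2-Ob, H2-DMb2 and H2-Oa, which regulate peptide loading and are strong in B cells, and H2-Ab1, a class II chain on all antigen-presenting cells, fell by 0.68, 0.62, 0.58 and 0.56. Cr2 and these 4 genes lost their calls without HDM replicate 2 or short-term replicate 5, and some without other libraries, with adjusted p of up to 0.0879 for Cr2 and 0.109 for H2-Oa. The T-cell list did not pass (median 1.24, camera adjusted p = 0.0717). Leaving out short-term replicate 3, whose T-cell list lay 3.41 log2 units above the other short-term libraries, the list was called lower, with a median of -0.16 (camera adjusted p = 0.0132, and adjusted p = 0.888 with an estimated correlation).

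Lists of monocytes and interstitial macrophages, neutrophils and the mitochondrial genome were also lower. The first had a median of -0.39 over 15 members, with 4 lower over all genes and 6 adjusted over the list alone (camera adjusted p = 2.7e-06, and adjusted p = 0.548 with an estimated correlation). Ly6c2, a surface marker of inflammatory monocytes, fell by 0.91 (SE 0.16, adjusted p = 0.0118), Ms4a7 by 0.86 and the lipid carrier Apoe by 0.61. Apoe lost its call without HDM replicates 2, 4 or 5 or short-term replicates 2 or 5 (largest adjusted p 0.0929, without short-term replicate 5). The median of this list was -0.18 without short-term replicate 3 and -0.19 without HDM replicate 5. The neutrophil list had a median of -0.28 over 14 members, with 3 lower over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00705, and adjusted p = 0.625 with an estimated correlation). Its called members were Mmp9 and Mmp8, matrix-degrading proteases stored in granules, and Retnlg, a secreted protein of neutrophils, at -0.62, -0.91 and -0.98, none of which passed without short-term replicate 5 (adjusted p = 0.0579, 0.0643 and 0.0616). The median of the neutrophil list was -0.10 without short-term replicate 3, -0.17 without short-term replicate 5, -0.44 without short-term replicate 2 and -0.55 without short-term replicate 4. All 7 tested mitochondrial genes lay below 0 with a median of -0.80, 4 of them lower over all genes and 6 adjusted over the list alone (camera adjusted p = 2.2e-06, and adjusted p = 0.515 with an estimated correlation). mt-Co1, a subunit of cytochrome oxidase, fell by 0.71, and mt-Nd1, mt-Nd4 and mt-Nd2, subunits of complex I, by 0.82, 0.75 and 0.96, and none of the 4 passed without HDM replicate 1, HDM replicate 2 or short-term replicates 1, 2 or 5 (largest adjusted p 0.0918, for mt-Nd2 without short-term replicate 5). Without HDM replicates 1 and 2, whose mitochondrial shares of 5.97% and 7.16% were the highest of the 15 libraries, the median was -0.35 and no member passed.

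Some members of the matrix, epithelial and endothelial lists were lower. Eln (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323) fell by 1.82 (SE 0.36, adjusted p = 0.0166), and Loxl2 and Lox, enzymes that cross-link collagen and elastin, fell by 0.66 and 0.64. Without short-term replicate 5 none of the 3 passed (adjusted p = 0.0502, 0.0826 and 0.116), nor without HDM replicates 1 and 2 (adjusted p = 0.0542 for Eln). These were the 3 called of 22 members of the matrix list, over all genes and adjusted over the list alone (median -0.32, camera adjusted p = 5.0e-05, and adjusted p = 0.677 with an estimated correlation). The type 2 alveolar epithelial (AT2) list had a median of -0.38 over 14 members, with 2 lower over all genes and 6 adjusted over the list alone (camera adjusted p = 7.7e-06, and adjusted p = 0.625 with an estimated correlation). Lpcat1, which makes surfactant lipid, fell by 0.55 (SE 0.11, adjusted p = 0.0176), and Cd36, a fatty acid carrier shared with endothelium and macrophages, by 0.50 (not called without HDM replicates 1, 2 or 5 or short-term replicates 1, 2 or 5, with adjusted p of up to 0.0730). Single members were called in the lists of epithelial junctions (Cldn18, a tight-junction protein, at -0.56), endothelium (Emcn, an endothelial surface sialomucin, at -0.57), fibroblasts (Cd44, a hyaluronan receptor also found on leukocytes, at -0.44) and MSC-secreted mediators (Cxcl12, a chemokine made by many stromal and endothelial cells, at -0.42). Without HDM replicate 2 none of these 4 passed, with the largest adjusted p over libraries left out at 0.0568 for Cldn18, 0.05001 for Emcn, 0.108 for Cd44 and 0.0802 for Cxcl12. Adjusted over the list alone, 4 members were lower for junctions, 1 for endothelium, 1 for fibroblasts and 5 for MSC mediators. The medians of these lists were -0.18, -0.12, -0.23 and -0.19, with camera adjusted p of 0.00153, 0.0157, 0.0334 and 0.00499. With an estimated correlation the adjusted p were 0.625, 0.887, 0.677 and 0.548.

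Several of these calls moved with short-term replicate 3, in which lung lists lay low: relative to the other short-term libraries, log2 ratios were -0.84 for the AT2 list, -0.97 for the matrix list and -0.92 for the endothelial list. Without it the lists of matrix (median -0.13, adjusted p = 0.0719), junctions (-0.04, 0.129), MSC mediators (-0.05, 0.0719), endothelium (0.04, 0.622), fibroblasts (-0.10, 0.137) and lymphatic vessels (-0.11, 0.306) were not called, and the AT2 median was -0.25 (adjusted p = 0.000684). The lymphatic list had a median of -0.25 with all libraries (0 of 6 members lower over all genes and 3 adjusted over the list alone, camera adjusted p = 0.0344, and adjusted p = 0.625 with an estimated correlation). The cell-cycle list, the only list called higher, had a median of 0.37 with no member past the test (Tyms, which makes thymidylate, at 0.65, adjusted p = 0.0681; camera adjusted p = 0.0157, and adjusted p = 0.913 with an estimated correlation). Without short-term replicate 3 its median was -0.001. Without HDM replicate 3 the endothelial (-0.07, 0.114), fibroblast (-0.11, 0.151), lymphatic (-0.22, 0.0650) and cell-cycle (0.31, 0.114) calls were lost, and without HDM replicate 2 the lymphatic call (-0.23, 0.0610). Without HDM replicate 5 the medians of the matrix and MSC lists were -0.20 and -0.13. Conversely the smooth-muscle list, not called with all libraries (median 0.21, adjusted p = 0.177), was higher without short-term replicate 3 (median 0.40, 6 of 11 members higher, camera adjusted p = 3.8e-06, and adjusted p = 0.260 with an estimated correlation).

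Among called genes with the lowest fold changes, Spon2, a secreted matrix protein that binds integrins (ENSMUSG00000037379, chromosome 5, 33198184 to 33218455), fell by 1.51 (SE 0.19, adjusted p = 0.00549), from 11.9 ± 2.87 to 4.13 ± 0.820 CPM (n = 5 each). Csf2 (ENSMUSG00000018916, chromosome 11, 54247271 to 54249667) fell by 1.33 (SE 0.24, adjusted p = 0.0118). For both, all 5 short-term libraries lay below the lowest HDM library. The collagenase Mmp13 (chromosome 9, 7272514 to 7283331) fell by 2.39 (SE 0.64, adjusted p = 0.0491), with values of 7.09 ± 5.08 against 37.5 ± 21.7 CPM (n = 5 each), and n-R5-8s1, annotated as a 5.8S ribosomal RNA, by 1.55. Among those with the highest fold changes, Sele, the endothelial selectin that captures leukocytes (chromosome 1, 164048234 to 164057677), rose by 1.42 (SE 0.33, adjusted p = 0.0264), from 2.58 ± 0.524 to 6.87 ± 3.27 CPM (n = 5 each). Fbp1, the gluconeogenic fructose-bisphosphatase (chromosome 13, 62864753 to 62888282), rose by 1.27 (SE 0.34, adjusted p = 0.0458). Serpina3m, a serine protease inhibitor whose close paralog Serpina3k overlaps it in the annotation, rose by 2.004, and the sodium channel subunit Scn2b by 1.22. AC154912.3 and AC154912.5, which lie within Fkbp5 on the same strand, rose by 1.89 and 1.85, and Mir7227, inside Arid1a, by 1.19. Whether reads of host genes were counted for these 3 is not given in the sources used here. Rag1 had a log2 fold change of 9.56 (SE 2.42, adjusted p = 0.0413), which fell to 2.33 (adjusted p = 0.096) without short-term replicate 3. Without that library AC154912.3 and Scn2b were at 1.16 and 0.80, and Mmp13 (adjusted p = 0.0839) and Mir7227 (adjusted p = 0.0632) did not pass. Mmp13 and Mir7227 each lost their call without 8 of the 10 libraries in turn (largest adjusted p 0.0984, without HDM replicate 2, and 0.0943, without HDM replicate 4), and Rag1 without 7. Of the other genes of this paragraph, Spon2, Csf2 and AC154912.5 passed whichever single library was left out, while Sele, Fbp1, Serpina3m, AC154912.3, Scn2b and n-R5-8s1 lost their calls without HDM replicate 4 and others (largest adjusted p 0.104, for Fbp1).

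Clock genes and targets of glucocorticoids, fixed as quality lists because hour of collection and stress move them, held some of the called genes with the smallest p. Cry1 and Per2, repressors of the molecular clock, rose by 0.81 (SE 0.11, adjusted p = 0.00549) and 1.04 (SE 0.17, adjusted p = 0.00929). Nr1d1, a clock repressor of another phase, fell by 1.14 (SE 0.20, adjusted p = 0.0109), from 121 ± 19.1 to 54.6 ± 15.8 CPM (n = 5 each). The circadian list had 3 members higher and 2 lower over all genes, or 8 and 3 adjusted over the list alone (median 0.29, camera adjusted p = 0.0564). In the glucocorticoid list, Zbtb16 rose by 1.11 while Angptl4 and Sgk1 fell by 1.004 and 0.54 (Zbtb16 not called without short-term replicate 5, adjusted p = 0.0508, nor Sgk1 without HDM replicates 2, 4 or 5 or short-term replicates 2 or 5, adjusted p of up to 0.0629; 2 higher and 2 lower over all genes, 3 and 4 adjusted over the list alone; median 0.18, camera adjusted p = 0.796). By fry's mixed test, which counts changes in either direction, both lists had an adjusted p of 3.7e-05. The hour of collection is not given in the sources used here.

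**Figure D2:**
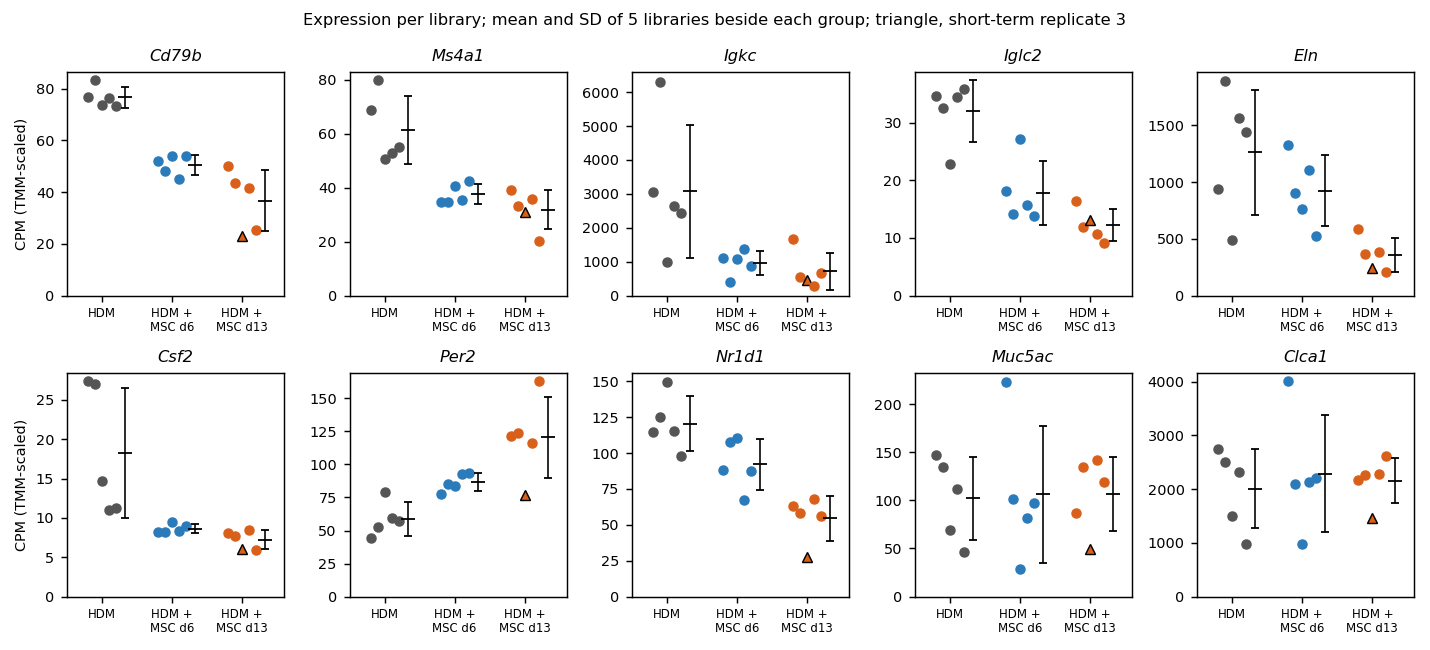
Expression of 10 genes in each of the 15 libraries (CPM scaled by TMM factors), by group, with the mean and SD of 5 libraries beside the points and short-term replicate 3 as a triangle. The B-cell genes Cd79b and Ms4a1 are lower in all 5 short-term libraries than in any HDM library, while Muc5ac and Clca1 overlap across groups.

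None of the 20 tested genes of the fixed asthma panel passed between the short-term group and HDM. Muc5ac, the main gel-forming mucin of inflamed airways, averaged 106 ± 38.3 against 102 ± 43.2 CPM (log2 fold change 0.06, SE 0.46, adjusted p = 0.95, n = 5 each). Clca1, another goblet-cell product, averaged 2159 ± 426 against 2011 ± 743 CPM (n = 5 each). The type 2 cytokines Il4, Il5 and Il13 had log2 fold changes of -0.08, 0.49 and 0.31, with SE of 0.34, 0.39 and 0.47. Their group means were at most 1.60 CPM in both groups, and with SE of this size sizeable changes would go undetected. The epithelial alarmins Il33 and Tslp were at -0.38 (adjusted p = 0.261) and 0.50 (SE 0.19), and Arg1, an enzyme of alternatively activated macrophages, was at -1.22 (SE 0.64, adjusted p = 0.263). Foxp3, which marks regulatory T cells, was at -0.44, and Col1a1, a fibrillar collagen, at -0.33. The list of type 2 cytokines and chemokines had a median of 0.10 (camera adjusted p = 0.815) with no member past the test over all genes or adjusted over the list alone. The mucus list had a median of 0.06, with a mean of -0.07 and a camera direction lower (adjusted p = 0.692), and 1 of its 13 members lower over all genes and adjusted over the list alone. The eosinophil list had a median of -0.30 (camera adjusted p = 0.070) with no member past over all genes, and 1 higher and 4 lower adjusted over the list alone. Ifng and Ly6g had too few counts to be tested.

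The comparison of the long-term group with HDM alone asks what MSCs given early in the challenge had left by its end. Fewer genes passed, and B-cell genes were again among the lower ones: Fcrla averaged 11.003 ± 1.23 CPM against 20.99 ± 3.66 CPM in HDM, and Cd180, a Toll-like receptor relative on B cells, 18.1 ± 1.57 against 32.1 ± 7.45 CPM (n = 5 each). Pou2f2, the B-cell transcription factor Oct-2, and Eomes, a transcription factor of natural killer and cytotoxic T cells, were lower as well. The mitochondrial ribosomal RNA mt-Rnr1 averaged 2292 ± 490 against 5731 ± 1098 CPM (n = 5 each). Lists of immediate early genes, ciliated cells, interferon response and smooth muscle were higher by camera at a preset correlation, with no member past the test and adjusted p = 0.987 for each with an estimated correlation.

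In edgeR's quasi-likelihood test 19 genes passed, 1 higher and 18 lower in the long-term group, with 2712 genes at an unadjusted p under 0.05, 10 genes changed by at least 1.5-fold and a median of 0.01 over all genes. The count was 0 without any one of HDM replicates 1, 2, 4 and 5 and long-term replicates 1, 3, 4 and 5, 1 without long-term replicate 2 and 68 without HDM replicate 3. It was 433 with short-term replicate 3 left out of the shared spread, 2 without HDM replicates 1 and 2 together and 0 with upper-quartile normalization, while DESeq2 called 663 genes and limma voom 487.

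Pou2f2 (ENSMUSG00000008496, chromosome 7, 25087344 to 25179726) fell by 0.89 (SE 0.15, adjusted p = 0.0382), from 25.9 ± 5.09 to 13.97 ± 1.68 CPM (n = 5 each). Fcrla fell by 0.93 (SE 0.16, adjusted p = 0.0382), Cd180 (chromosome 13, 102693558 to 102739629) by 0.83 (SE 0.14, adjusted p = 0.0382) and Eomes (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132) by 0.85 (SE 0.14, adjusted p = 0.0382). Eomes averaged 2.44 ± 0.223 against 4.41 ± 0.731 CPM (n = 5 each). Lrrc8c, a subunit of volume-regulated anion channels, fell by 0.70, and Cherp, a nuclear protein of RNA processing and calcium handling, by 0.59. For these 6 genes all 5 long-term libraries lay below the lowest HDM library. Mir6236, whose annotated locus resembles ribosomal RNA, fell by 2.39 (SE 0.41, adjusted p = 0.0421) and mt-Rnr1 by 1.32 (SE 0.22, adjusted p = 0.0382). Gm12940, an uncharacterized transcript named after its values were seen because it was the only gene called higher, rose by 0.80 (SE 0.14, adjusted p = 0.0421), from 6.69 ± 1.19 to 11.6 ± 1.47 CPM (n = 5 each). None of these 9 genes passed without any one of HDM replicates 1, 2, 4 or 5 or long-term replicates 1, 3, 4 or 5, with adjusted p of up to 0.178 without long-term replicate 5.

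All 13 members of the B-cell list were again below 0, with a median of -0.61, 1 lower over all genes and 10 adjusted over the list alone (camera adjusted p = 1.3e-15, and adjusted p = 0.355 with an estimated correlation). Ms4a1 and Cr2 had log2 fold changes of -0.71 (adjusted p = 0.0789) and -1.05 (adjusted p = 0.0892). The plasma-cell list had a median of -0.53 with 14 of 17 members below 0, none past the test over all genes and 3 adjusted over the list alone (camera adjusted p = 9.7e-05, and adjusted p = 0.868 with an estimated correlation). Igkc was at -1.67 (adjusted p = 0.161), Ighg2b at -1.33 (adjusted p = 0.104) and Iglc2 at -0.85 (adjusted p = 0.0865). Of 156 variable segments 121 lay below 0 with a median of -1.004 and none called. The follicle list had a median of -0.56 (3 lower adjusted over the list alone, camera adjusted p = 0.000655, and adjusted p = 0.377 with an estimated correlation). The MHC class II list had a median of -0.18 (none called over all genes or adjusted over the list alone, camera adjusted p = 0.0150, and adjusted p = 0.987 with an estimated correlation), with H2-Ob at -0.46 (adjusted p = 0.157). The MHC class II call was lost without HDM replicate 5 (adjusted p = 0.0716) and without long-term replicate 2 (adjusted p = 0.0896). Without HDM replicates 1 and 2 the B-cell median was -0.53 and the follicle median -0.33.

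The mitochondrial list had a median of -0.82 over 7 members, none lower over all genes and 6 adjusted over the list alone (camera adjusted p = 7.6e-11, and adjusted p = 0.355 with an estimated correlation), with mt-Nd2 at -1.12 and mt-Nd5 at -1.21 (adjusted p = 0.0769 each). Without HDM replicates 1 and 2 its median was -0.42. The natural killer list had a median of -0.31, with Eomes its only member past the test over all genes or adjusted over the list alone and Ncr1 at -0.65 (adjusted p = 0.304; camera adjusted p = 0.0249, and adjusted p = 0.987 with an estimated correlation). The list of mast cells and basophils had a median of -0.24 with no member past either test (camera adjusted p = 0.0492, and adjusted p = 0.377 with an estimated correlation). No member of the 4 lists called higher passed over all genes or adjusted over the list alone. The immediate early list had a median of 0.36 (camera adjusted p = 0.00244), with the heat shock genes Hspa1a at 1.15 (adjusted p = 0.157) and Hspa1b at 1.09 (adjusted p = 0.18). The ciliated list had a median of 0.21 (camera adjusted p = 0.00517), the interferon list 0.27 (0.0150) and the smooth-muscle list 0.18 (0.0492), and with an estimated correlation each of these 4 lists had adjusted p = 0.987. Examples are Tekt1, a protein of ciliary tubules, at 0.46, the interferon-induced genes Mx2 and Ifit3 at 0.77 and 0.67, and the contractile genes Tagln and Cnn1 at 0.53 and 0.46 (adjusted p from 0.208 to 0.262).

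Most of the smaller list calls were lost when some single library was left out, while the immediate early call was not. Without HDM replicate 1 the natural killer (median -0.20, adjusted p = 0.0861) and mast-cell (adjusted p = 0.110) calls were lost, and without HDM replicate 3 the natural killer (-0.13, 0.543) and smooth-muscle (0.119) calls. Without HDM replicate 4 the smooth-muscle call was lost (0.0656), and without HDM replicate 5 those of ciliated cells (0.114), mast cells (0.112), smooth muscle (0.212) and interferon response (0.0716). Without long-term replicate 1 smooth muscle (0.124) was lost and the mast-cell median was -0.48, and without long-term replicates 2 and 4 the mast-cell call was lost (0.0538 and 0.0530). Without long-term replicate 3 the lists of natural killer cells (0.102), mast cells (0.0553), smooth muscle (0.0640) and interferon (0.0751) were not called, nor without long-term replicate 5 (-0.20 and 0.152, 0.0788, 0.0565 and 0.0773). The ciliated median was 0.34 without HDM replicate 3, and the immediate early median was 0.18 without HDM replicate 2 and 0.04 (adjusted p = 0.655) without HDM replicates 1 and 2.

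None of the 20 tested panel genes passed between the long-term group and HDM. Foxp3 was at -0.75 (SE 0.23, adjusted p = 0.157), with 3.34 ± 0.687 against 5.63 ± 1.80 CPM (n = 5 each). Tslp was at 0.39, Il33 at -0.28, Muc5ac at 0.06, Clca1 at 0.19, Epx, a peroxidase of eosinophils, at 0.50 and Col1a1 at -0.01. The mitochondrial share of the counts was 3.14 ± 0.277% in the long-term group and 5.57 ± 1.11% in HDM, and the share of the 10 most abundant genes was 8.61 ± 0.454% against 10.4 ± 0.807% (n = 5 each). Both had an exact two-sided permutation p of 0.00794, the smallest that relabeling 5 against 5 can give, and 0.0714 adjusted over 18 tests. The immunoglobulin share was 0.391 ± 0.158% in the long-term group (exact permutation p = 0.0397, 0.119 adjusted). The mitochondrial share of the short-term group was 3.68 ± 0.835% (exact permutation p = 0.0238 against HDM, 0.0857 adjusted), with short-term replicate 3 at 5.08%. None of the 18 composition tests passed after adjustment with all libraries, while without HDM replicate 3 the long-term differences in the share of the 10 most abundant genes, the mitochondrial share and the immunoglobulin share each had an adjusted p of 0.0476 by the exact two-sided permutation test. Most of the mitochondrial share is ribosomal RNA (mt-Rnr1 and mt-Rnr2), which took 3.63 ± 0.592% of the counts in HDM, 1.95 ± 0.246% in the long-term group and 2.48 ± 0.718% in the short-term group (n = 5 each). The share is therefore no measure of mitochondrial gene expression. It could also move with how much ribosomal RNA was carried over, which was not tested. The mitochondrial shares cover only part of that genome: 6 of its 13 protein genes held at most 11 counts in any library, for a reason not given in the sources used here.

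**Figure D3:**
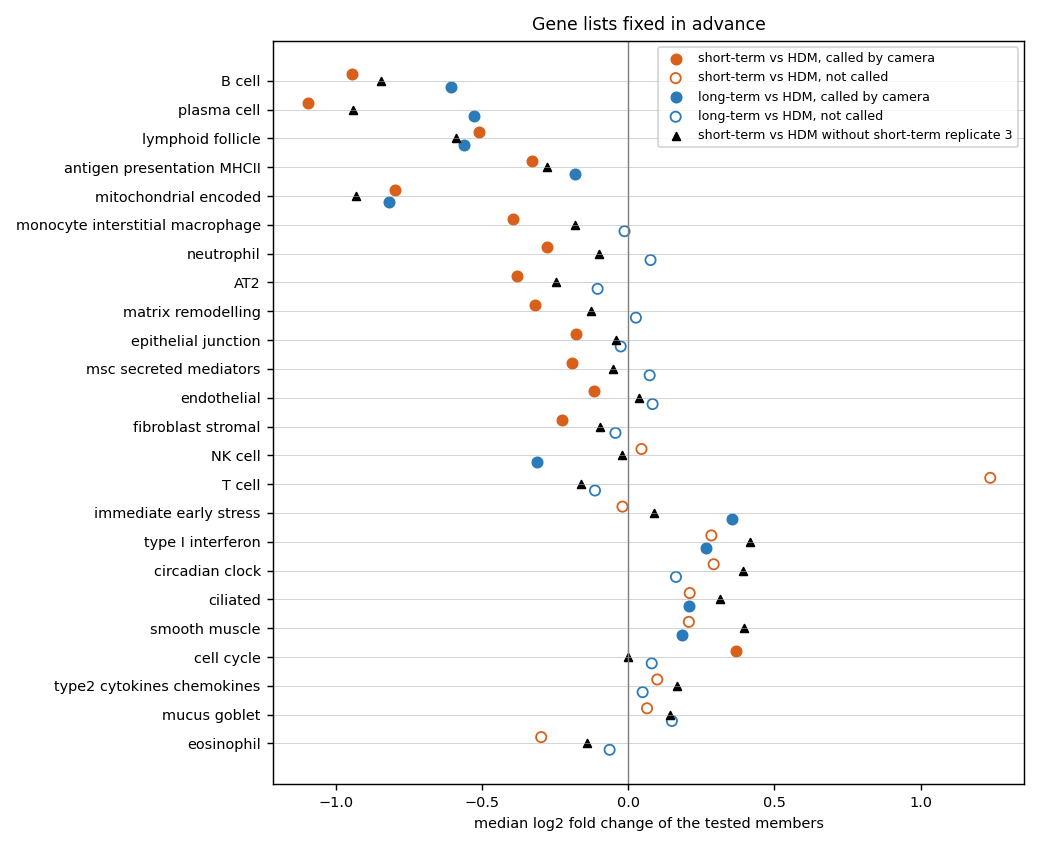
Median log2 fold change of the tested members of 24 gene lists, for the short-term group (orange) and the long-term group (blue) against HDM, filled where camera called the list, with black triangles for the short-term group without short-term replicate 3. The B-cell list is lower in both groups, at -0.94 and -0.61, and the cell-cycle median of 0.37 falls to -0.001 without that library.

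The comparison of the short-term with the long-term group is the direct test of whether the time of MSC administration mattered. Spon2 had the smallest p, with 4.13 ± 0.820 CPM in the short-term group and 9.22 ± 1.504 CPM in the long-term group (n = 5 each, log2 fold change -1.15, SE 0.19, adjusted p = 0.26), and all 5 short-term libraries lay below every long-term library. Lists of matrix, monocytes, type 2 alveolar cells, plasma cells and neutrophils were lower in the short-term group by camera at a preset correlation (adjusted p = 0.575 for each with an estimated correlation), though no member of any list passed over all genes. The matrix and AT2 medians shrank from -0.34 and -0.31 to -0.21 and -0.16 without short-term replicate 3. No gene passed edgeR's quasi-likelihood test, with 1514 genes at an unadjusted p under 0.05, while DESeq2 called 2 genes and limma voom 1.

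Besides Spon2, the genes with the smallest p in each direction, none past the test (adjusted p = 0.623 each), were as follows. Higher in the short-term group were Zbtb16 at 0.99, Cry1 at 0.49, Hif3a, a regulator of the hypoxia response, at 1.01, Rag1 at 9.66 and Mir3109, inside Anxa2, at 0.82. Lower were AC133523.4 at -0.97, Afap1l2, an actin-associated adaptor protein, at -0.41, Itgb6, the epithelial integrin subunit that activates TGF-beta, at -0.71, and the cell adhesion gene Nrcam at -0.79. Without short-term replicate 3 the value of Rag1 was 2.42.

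Of 47 lists, 16 were called lower and 4 higher in the short-term group. With an estimated correlation the adjusted p of the 20 lists ran from 0.575 to 0.789, and fry's smallest adjusted p over the lists was 0.448. The matrix list had a median of -0.34 with all 22 members below 0 and 1 lower adjusted over the list alone (camera adjusted p = 1.0e-09), and Eln and Loxl2 were at -1.37 (SE 0.35) and -0.45. The monocyte list had a median of -0.36 (3.9e-08), with Cx3cr1, the fractalkine receptor, at -0.59 and Ly6c2 at -0.49. The AT2 list had a median of -0.31 (2.4e-07) with 1 member lower adjusted over the list alone, and Lpcat1 at -0.40. Plasma cells (-0.43, 1.5e-05) and B cells (-0.24, 4.7e-05) were lower, with Iglc2 at -0.54 and Cd79b at -0.46, as were neutrophils (-0.32, 4.1e-05), with Mmp9 at -0.36 and S100a9, an alarmin of neutrophils, at -0.76. The immediate early list had a median of -0.34 (2.6e-05), with the transcription factor Egr1 at -0.43. MSC mediators (-0.21, 2.6e-05), endothelium (-0.24, 2.6e-05), MHC class II (-0.22, 4.4e-05), platelets (-0.50, 0.000242), junctions (-0.17, 0.000730), fibroblasts (-0.14, 0.00194), type 1 alveolar cells (AT1, -0.16, 0.00432), complement (-0.15, 0.00838) and erythroid cells (-0.28, 0.00838) were called lower with no member past either adjustment. Called higher were T cells (1.44, 0.000444), natural killer cells (0.26, 0.00393), thymocytes (3.10, 0.00432, 7 members adjusted over the list alone) and cell cycle (0.31, 0.0468), with Dntt, the polymerase that adds bases at antigen receptor joints, at 6.88 and Cd8a at 3.63.

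Many of these lists moved with short-term replicate 3. Without it the lists of T cells (median -0.07, camera adjusted p = 0.0942), thymocytes (0.12, 0.508), junctions (-0.06, 0.147), AT1 (-0.04, 0.437), complement (-0.001, 0.399) and erythroid cells (-0.23, 0.0942) were not called, and the cell-cycle list was called lower (-0.15, 0.00687). With an estimated correlation, no list was called without that library. Dntt and Cd8a were then at 0.26 and 0.17. Without it the medians were -0.21 for matrix, -0.16 for AT2, -0.16 for B cells, -0.12 for MHC class II, -0.13 for MSC mediators, -0.18 for immediate early genes, -0.09 for endothelium and -0.05 for fibroblasts, each still called. Without short-term replicate 1 the medians were -0.37 for B cells and -0.74 for plasma cells, and without short-term replicate 5 -0.12 for B cells and -0.22 for fibroblasts. Without short-term replicate 4 they were -0.49 for neutrophils, -0.26 for AT1, -0.32 for complement and -0.47 for erythroid cells, and cell cycle was not called (adjusted p = 0.108). Without long-term replicate 2 cell cycle was not called (0.124). Without long-term replicate 3 it was not called (0.118) and the AT1 median was -0.10. Without long-term replicate 4 it was not called (0.109), nor were erythroid cells (-0.13, 0.228), and the plasma-cell median was -0.27. Without long-term replicate 5 natural killer cells were not called (0.16, 0.0607).

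The effects of both MSC groups share the HDM libraries, so some likeness between them arises from HDM alone. Of the 19 genes called in the long-term group, 17 were also called in the short-term group in the same direction, 16 lower and 1 higher, an overlap for which no expected value under shared HDM libraries was computed. Across the 19562 tested genes, which are not independent replicates, the log2 fold changes of both comparisons correlated with Pearson's r of 0.531. In 50 simulations with neither MSC group changed, r averaged 0.499 (range 0.462 to 0.518), with a covariance of 0.0349 against 0.0812 observed. Without short-term replicate 3 the observed r was 0.757, against 0.473 (0.441 to 0.497) in simulations. The simulations drew genes independently and with the same spread in all groups, while HDM replicates 1 and 2 lay apart from the other libraries. Their range therefore leaves out likeness that comes from such HDM libraries, and an r above it does not show an effect of the MSCs. With the HDM libraries split so that each comparison used different ones, the median r was 0.298 (range -0.047 to 0.367). The F test over all 3 groups called 314 genes. That count was 830 without short-term replicate 3, 14 without HDM replicate 2, 30 without HDM replicate 1, 37 without HDM replicate 4 and 181 without HDM replicate 5. It was 195, 78 and 60 without short-term replicates 1, 2 and 5, and 98, 131, 108, 103 and 32 without long-term replicates 1 to 5.

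**Figure D4:**
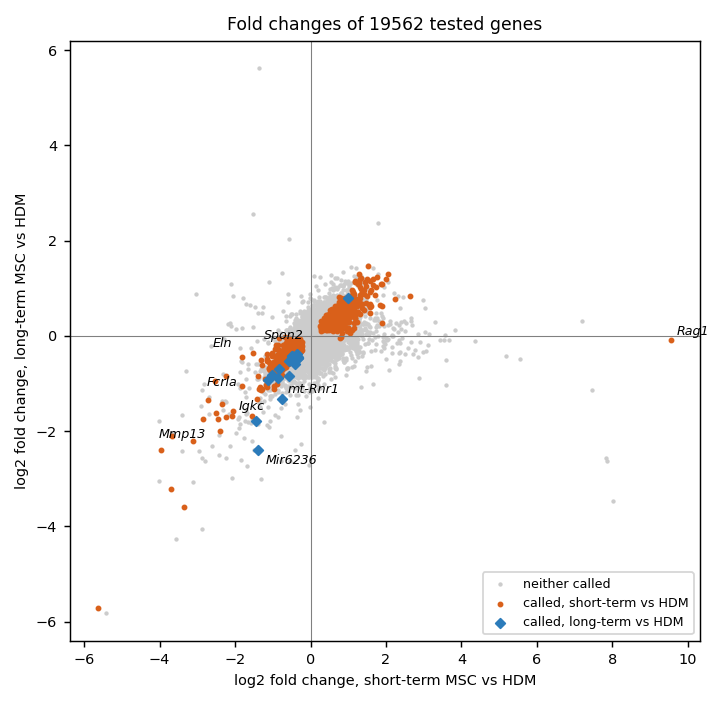
Log2 fold change against HDM of 19562 tested genes, short-term group on the horizontal axis and long-term group on the vertical axis, with called genes in colour. Of the 19 genes called in the long-term group (blue diamonds), 17 were also called in the same direction in the short-term group. Orange marks genes called in the short-term group but not in the long-term group.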

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

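The tests of thymus tissue, of a wrong label and of less lymphoid tissue of every kind were chosen only after the result was seen. For GC content, which of its planned criteria to give as deciding was also chosen after both were seen. Within groups of 5 libraries, 31 of 258 sets of values had a lowest or highest library set apart beyond Dixon's 95% limit for its ratio. For independent sets chosen without these data, chance would give about 1 in 20, or 12.9. Many sets were lists and genes called in these same data, some through short-term replicate 3, and sets share genes. The 31 can therefore not be weighed against 12.9. Of the 31, 19 concern short-term replicate 3 and 12 other libraries.

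Short-term replicate 3 was set apart in genes detected (ratio 0.9504), share of the 10 most abundant genes (0.9465) and share of satellite transcripts (0.9998). It was highest for the T-cell (0.826), thymocyte (0.8427) and mitochondrial (0.764) lists, and lowest for the lists of AT1 (0.8495), AT2 (0.8158), endothelium (0.889), epithelial junctions (0.8497), lymphatic vessels (0.8823) and smooth muscle (0.738). Among genes it was highest for AC154912.3 (0.8351), AC154912.5 (0.8267), Mir7227 (0.8415), Mki67 (0.8877), Rag1 (0.9966) and Scn2b (0.7971), and lowest for Spon2 (0.7655).

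Of the other libraries, HDM replicate 2 had the highest total count of its group (0.7672) and the lowest Il17a (0.7175). HDM replicate 3 was lowest for the plasma-cell list (0.7469), Iglc2 (0.7394) and Nrcam (0.7576) and highest for Zbtb16 (0.7247). Short-term replicate 1 was highest for the immunoglobulin share (0.7153) and Igkc (0.7266), short-term replicate 4 for Cxcl5 (0.7891) and Il10 (0.7278), and long-term replicate 5 was lowest for the lymphatic list (0.7554) and highest for Serpina3m (0.7719). The effects of both MSC groups differed in 20 lists by the direct test of short-term against long-term, and in 0 of them with an estimated correlation.

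The thymocyte genes and satellite transcripts of short-term replicate 3 are the first pattern weighed. Thymus tissue in the lobe sample stays open: 87.5% of the tested thymocyte list lay at least 4 times above the other short-term libraries, but these genes are the pattern itself, so the value tests nothing. Genomic DNA in the library is a candidate source of the satellite counts. Among genes nearly silent elsewhere, the counts of this library followed transcript length (Spearman rho 0.524), which does not tell genomic DNA from other low-level reads. Genes of the Y chromosome had counts in 4 of 1562 cases, against 2 to 6 in the other libraries. In female mice they stay nearly empty whatever the source, so that value decides nothing. A library of another tissue under a wrong label is argued against by the AT2 list, at a log2 ratio of -0.84 to the other short-term libraries. No biological explanation was tested.

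The lower B-cell and plasma-cell genes of the MSC groups are the second pattern. For the B-cell list, HDM replicates 1 and 2 alone are argued against, since without them its median was -0.527 in the long-term group and -0.770 in the short-term group. Transcript length bias is argued against for that list by a median of -0.92 in the short-term group after a length correction. The plasma-cell list was not used in these tests, so for it both explanations stay open. Less lymphoid tissue of every kind is argued against as the whole cause by a T-cell median of -0.162 without short-term replicate 3, against -0.847 for B cells, although that T-cell list was itself called lower (adjusted p = 0.0132) and the margin to the bound set for the test was small. An effect of the MSCs stays open as a hypothesis, as do less B-cell-rich tissue in the lobes taken and differences in handling between groups, for which the sources used here give no batch. Mitochondrial ribosomal RNA, a possible sign of RNA or library quality, was also higher in HDM (3.63% of counts) than in the long-term (1.95%) and short-term (2.48%) groups, and its link to the B-cell genes was not tested.

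The count of 937 genes in the short-term group is the third pattern. Of 100 splits of the 10 libraries into 5 and 5, only the real one (1 of 100) gave as many genes, the highest other giving 134. That rank argues against chance assignment of libraries but does not exclude it. Every split kept the long-term libraries in the fit. With only the 10 libraries fitted, the real split gave 0 genes. For the long-term group 1 of 100 splits gave 19 genes, the highest other giving 2. For short-term against long-term the real split gave 0 genes with edgeR (1514 at an unadjusted p under 0.05, DESeq2 2, limma voom 1), so that 100 of 100 splits gave at least as many by necessity and the count says nothing about chance (highest other 1). Transcript length bias is argued against by a rho of -0.077 between fold change and length, though a length correction kept 74.7% of the calls, and GC bias as the whole cause by 89.8% of calls kept after a GC correction, though fold changes had a rho of -0.161 with GC content.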

How the results depend on the processing

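All fits that leave out HDM replicates 1 and 2 together, that leave out short-term replicate 3 together with another change, and the length and GC corrections were chosen after the result was seen. Counts are given as short-term against HDM, long-term against HDM and any group (937, 19 and 314 in the fit of the report). They were 779, 0 and 181 with upper-quartile scaling, 208, 2 and 65 with no filter (median log2 fold change of all genes 0.454 for short-term against HDM), 2136, 663 and 1563 with DESeq2, 2412, 487 and 1397 with limma voom, and 2885, 833 and 1855 with 1 surrogate variable. They were 183, 2 and 1 without HDM replicates 1 and 2, 2279, 492 and 1020 without those and short-term replicate 3, 2466, 1550 and 2190 with DESeq2 without short-term replicate 3, and 1576, 167 and 694 with a GC correction. With only the compared groups fitted, the first 2 were 0 (3494 at an unadjusted p under 0.05) and 36, and at a fold of at least 1.5 they were 464 and 10. The short-term count was 152 with only both groups and short-term replicate 3 left out, and the long-term count was 433 with that library out of the shared spread. Short-term against long-term (0 with edgeR) gave 2 with DESeq2, 4 with DESeq2 without short-term replicate 3 and 1 with voom. Leaving out each library in turn gave 160 to 1294, 0 to 68 and 14 to 830 genes. Lists called (15 for short-term against HDM, 11 for long-term against HDM, 20 for short-term against long-term) were 0 in all 3 with an estimated correlation and 4, 0 and 0 with fry. The 4 lists called with fry were B cells (fry adjusted p = 0.00638), plasma cells and follicles (0.0161 each) and MHC class II (0.0408). Without short-term replicate 3, the estimated correlation gave 0 and fry 8 for short-term against HDM, and both gave 0 for short-term against long-term. With no filter 23 lists were called for short-term against HDM and 31 for short-term against long-term, and leaving out each library gave 7 to 13 for long-term against HDM. The correlation of both effects (0.531) was 0.597 by Spearman, 0.436 at 10 CPM or more, 0.757 without short-term replicate 3, 0.623 without HDM replicates 1 and 2, 0.775 without all 3, and a median of 0.298 with split HDM libraries (0.364 without short-term replicate 3), and ranged from 0.530 to 0.583 with each HDM library left out. Composition in the long-term group, with each library left out, ranged from -2.03 to -1.54 for the 10 most abundant genes, -2.76 to -2.04 for mitochondrial genes and -0.628 to -0.324 for immunoglobulin. List medians that changed sign were those of the cell cycle (-0.001 to 0.548) and endothelium (-0.174 to 0.036) for short-term against HDM. For short-term against long-term they were T cells (-0.069 to 1.673; -0.095 with 1 surrogate variable, -0.083 without all 3), cell cycle (-0.150 to 0.439; -0.219 and -0.164) and complement (-0.316 to -0.001; 0.003 with 1 surrogate variable). Of the other values of called lists, 246 were within the same call and 22 weaker for short-term against HDM, 177 and 32 for long-term against HDM, and 326 and 27 for short-term against long-term. Of the values of the 51 called genes followed for the short-term group, 286 of the planned ones were weaker and 681 the same, and of the 9 for the long-term group 99 and 72. The cause of these changes was not tested.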

Other observations

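The list values without short-term replicate 3 were chosen after the result was seen where they add an estimated correlation or fry. The clock genes Cry1, Per2 and Nr1d1 and the glucocorticoid targets Zbtb16, Angptl4 and Sgk1 were among the called genes of the short-term group. In the long-term group against HDM no member of either list passed over all genes. Adjusted over the list alone, 4 clock genes were higher and 2 lower there, and 1 glucocorticoid target was higher and 3 lower. Adjusted p by fry's mixed test, which counts changes in either direction, were 0.0736 and 0.0742 in that group. Without short-term replicate 3 the circadian list was called higher (median 0.39, camera adjusted p = 0.0046, and adjusted p = 0.333 with an estimated correlation). A difference in the hour of collection between groups could move such genes, as could an effect of the MSCs, and the hour is not given in the sources used here. The smooth-muscle list (median 0.395) and the ciliated list (0.313) were also called higher without that library, with adjusted p of 0.260 and 0.656 with an estimated correlation, and which of airway sampling or cell state moved them was not tested. Only 7 of the 13 mitochondrial protein genes had enough counts to be tested, and the other 6 held at most 11 counts in any library. Whether reads of these genes were removed before the table was made is not given in the sources used here, so the mitochondrial list and shares describe part of that genome.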
